A study of Danio rerio with 4 samples.

How the data were processed

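Single-cell 3′ RNA sequencing was carried out on dissociated head tissue of zebrafish embryos at 48 hours after fertilisation, in 2 wild-type libraries (WT) and 2 libraries labelled as tet2 and tet3 double knockout (KO). Each library is a droplet-based preparation in which a unique molecular identifier (UMI) marks each captured transcript. The deposited matrices hold raw UMI counts per gene and barcode, 1 library per matrix, and the authors made them with Cell Ranger 6.1.1 and the danRer11 genome build, per the submitters' processing notes. The gene annotation release, the rule by which barcodes were called as cells and any later filter are not given in the sources used here. The matrices list 25107 genes, of which 505 share their symbol with another gene and were named by symbol and Ensembl identifier. The reference table at hand describes another assembly than danRer11, so no coordinates are given.

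The files held 21173 and 15040 barcodes for the WT libraries and 16219 and 14857 for the KO libraries, with 176975307, 132626773, 185344586 and 179884343 UMIs. Cells with at least 500 genes, at least 1000 UMIs and a mitochondrial share of at most 10% passed, which left 16742, 11592, 13419 and 12489 cells. Doublets were scored with Scrublet in each library. Its automatic threshold marked 2.33 and 1.31% of the WT cells but 21.2 and 22.9% of the KO cells. The cells with the highest scores were therefore removed at the same expected rate in every library, 0.8% per 1000 cells, which marked 13.4, 9.27, 10.7 and 9.99%. That rule was chosen after seeing the data, and the automatic threshold was run as an alternative. Kept were 14500 and 10517 WT cells and 11978 and 11241 KO cells, with median UMIs per cell of 5505.5, 6542, 7031 and 7304.

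Counts of the kept cells were log-normalised, and 3000 variable genes, 50 principal components, 20 neighbours and Leiden clustering at resolution 1 (seed 7) gave 54 clusters (scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and Python 3.11.15). No authors' annotation of cells was used here. Clusters were named from marker genes fixed before the data were examined. A name needed at least 3 markers with a log2 fold change of at least 1 over other cells, each in at least 20% of cells. A cluster stayed unnamed where its top 10 genes held more markers of another class than of its own. It also stayed unnamed where its mean standardised marker level was under 0.5. Cluster 26, for example, had 13 basal epidermis markers but stayed unnamed. Every class name in the text means a class with markers like that cell type. Clusters that met no name kept their number, and so did clusters of a named class, such as neuron or neural progenitor, when another cluster with the same best match was left unnamed, since the class would have been incomplete. A cluster whose median UMI count was low against the rest of its libraries needed at least 2 of its own markers among its top 10 genes. This minimum was set after seeing the data and left cluster 17, with 0.0360% of the WT cells and 4.11% of the KO cells, unnamed. The best match of cluster 17 was lens cell, and its top 10 genes were crystallins. Cluster 0, also low in UMIs and unnamed, with neuron as its best match, held 17.1% of the WT cells and 0.254% of the KO cells.

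The library was the unit of replication. Raw counts were summed per library over all kept cells (whole head) and per class or numbered cluster with at least 20 cells in every library, which gave 12 classes and 22 clusters. Sums were tested with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM scaling, quasi-likelihood F-test, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg within each fit at 0.05. Fold changes are KO over WT with 2 libraries per genotype, and levels are CPM, counts scaled by effective library size. Exact permutation of 2 against 2 libraries cannot go below p = 0.333, so all p-values rest on the model. The labels do not say that the libraries came from separate clutches, so p-values measure only the spread between these libraries, which may be technical. Genotype was also not crossed with any batch, collection or strain given in the labels.

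Where a gene had 0 counts in 1 genotype, the fold is a lower bound from a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of pooled CPM is given with its 95% counting interval, and intervals and floors cover counting error only. A total of 26 gene lists and 35 lists of cell type markers, all fixed before the data were examined, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. Setting genes with 0 counts in 1 genotype at their bound moved no list median at 2 decimals.

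Shares of cells were tested with edgeR on cells per class, with the total kept cells of the library as its size. A share was compared only where at most 25% of the tested markers of the class changed at least 2-fold inside it at an adjusted p under 0.05, a rule set after seeing the data, and 5 classes met it. A class with fewer than 20 cells in any library had no marker tested and was not compared. Named genes followed a rule written before the data were examined. For whole heads, it took the 10 genes with the largest rise and the 10 with the largest fall. They needed an adjusted p under 0.05, a mean of at least 10 CPM in 1 genotype, no overlap between the libraries of the genotypes, and a gene symbol that is not a clone name. The rule took 6 and 6 genes for arch mesenchyme and 1 and 1 for each other class. Added to these were tet1, tet2 and tet3, the up to 4 members with the smallest p of each list, and up to 8 called members of each BMP list in arch mesenchyme. Other names are marked as chosen after their values were seen.

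The tests were first run on simulated counts drawn from the real means and library sizes of whole heads and arch mesenchyme. The other classes, the clusters and fry were not simulated. For whole heads (20849 genes), edgeR recovered 37.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 89.4% of those changed 4-fold, with 22 false calls, 14.5% of its calls and thus above the level of 0.05. For arch mesenchyme (10954 genes), the recovered shares were 20.9, 52.2 and 74.2%, with 4 false calls (3.92%). In whole heads, camera called the planted list and none of 30 unchanged lists, and the test of shares found 8 of 8 classes changed 2-fold and none of 39 unchanged ones. Genes were drawn independently of each other and few were changed. The simulation thus cannot show how camera fares with correlated genes, or how scaling fares when most genes change. For shares, the spread was set in advance and rises and falls were balanced, unlike in the data. Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2-style size factors (RLE), no filter on low counts, doublets kept, all deposited barcodes, equal numbers of cells per class, Leiden resolution 2, TMM over classes, the replicate number as a block, and each library left out in turn. Added after seeing the data were the automatic Scrublet threshold, whole heads without erythroid cells or without clusters of low UMI count, all head mesenchyme clusters pooled, and a crossed replicate block.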

Results

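To examine what loss of tet2 and tet3, which encode enzymes that oxidise 5-methylcytosine, changed in the embryonic zebrafish head, transcriptomes of single cells were compared between WT and double-knockout heads at 48 hours after fertilisation. The series title names a TET-BMP axis, so BMP genes and the arch mesenchyme, which forms the jaw skeleton, received the fuller account. After filtering, 126718677 and 104704225 UMIs from 14500 and 10517 cells represented WT replicates 1 and 2. KO replicates 1 and 2 were represented by 141539732 and 139068652 UMIs from 11978 and 11241 cells. The median mitochondrial share per kept cell was 2.66 and 2.51% in WT and 1.47 and 1.45% in KO.

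Transcripts of both targeted genes were lower in KO heads but were still detected. Expression of tet2 was 88.4 and 93.0 CPM in the WT libraries and 58.5 and 60.5 CPM in the KO libraries, a log2 fold change of -0.61 (SE 0.05, adjusted p = 0.000169, edgeR). Expression of tet3 was 286 and 298 CPM in WT and 137 and 139 CPM in KO (log2 fold change -1.08, SE 0.04, adjusted p = 1.48e-05). The remaining family member, tet1, was at 9.69 ± 0.190 CPM in WT and 9.07 ± 0.484 CPM in KO (mean ± SD, n = 2) and was not called by edgeR (adjusted p = 0.186). Of the 24 classes and clusters in which it was tested, it was called lower in 1 and higher in 3. Across 34 classes and clusters, tet3 was called lower in 31 and tet2 in 16, with fitted log2 fold changes from -2.25 to -0.21 and from -1.64 to 0.18. The 3′ tags counted here check the knockout only if they lie in the deleted part of each gene, which is not given in the sources used here, and tags outside it check nothing.

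**Figure D1:**
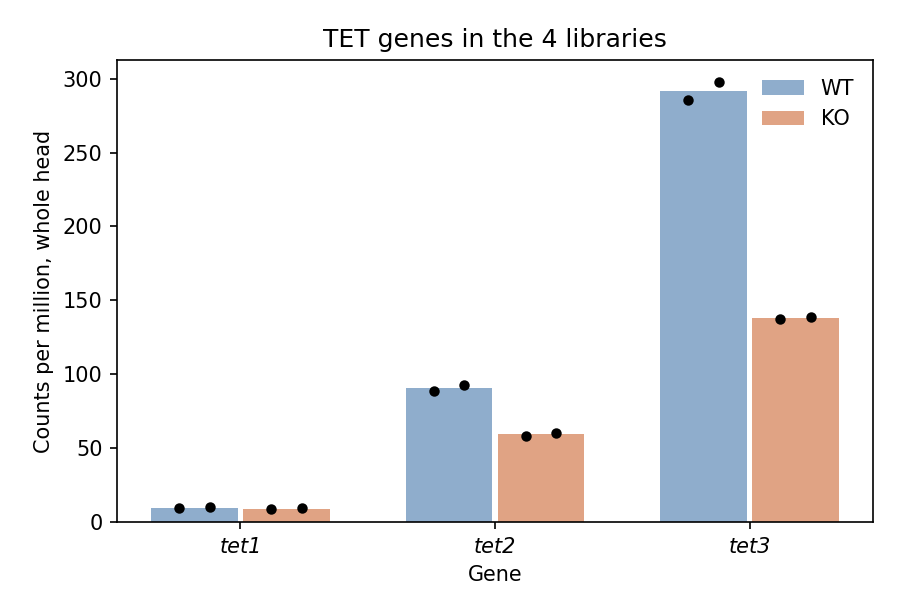
Expression of tet1, tet2 and tet3 in whole heads, in CPM, with bars at the mean of each genotype and 1 point per library (2 WT, 2 KO). The KO points of tet2 and tet3 lie below both WT points, while the tet1 points of both genotypes lie between 8.73 and 9.82 CPM.

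The 10 genes that fell most in whole KO heads included opsins and a transducin subunit of photoreceptors. Rhodopsin (rho, the rod opsin) fell from 58.0 ± 2.87 CPM to 3 UMIs over both KO libraries, a ratio of 5004 (95% counting interval 1712 to 24268). Losses of similar rank were found for gnb3a (147 ± 11.7 to 0.244 ± 0.0259 CPM, 599-fold), the cone opsins opn1sw1 (297-fold) and opn1lw2 (296-fold), and gngt2b, a cone transducin subunit (228-fold). The G protein subunit gene gnb3a was a top gene of cluster 15, with the bipolar cell marker vsx1, and not of the cone-like cluster 20. Cluster 15 held 587 and 496 WT but 3 and 0 KO cells, and cluster 20 held 508 and 382 WT but 17 and 15 KO cells. Top genes of cluster 20 included gngt2b, opn1lw2 and ckmt2a. The falls of these genes and of gnb3a thus mix any change within cells with the smaller number of such cells. The neuropeptide genes vipb (15.25 ± 2.29 to 0.0465 CPM, 321-fold) and oxt, which encodes oxytocin (10.1 ± 4.78 to 0.0388 ± 0.0112 CPM, 254-fold), also fell. So did ckmt2a, a mitochondrial creatine kinase (453-fold), epd, or ependymin (33.6 ± 17.3 to 0.0854 ± 0.0553 CPM, 390-fold), and the chemokine gene ccl35.1 (75.8-fold). Adjusted p-values of these 10 genes lay between 4.75e-06 and 0.000126 (edgeR, n = 2 per genotype).

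Among the genes that rose was lin28a, an RNA-binding regulator of developmental timing, from 12.2 ± 0.203 to 314 ± 11.09 CPM (25.6-fold, adjusted p = 4.75e-06). Within the 34 classes and clusters, lin28a was called higher in 32 and lower in 0, so its rise was not confined to whole-head sums. The embryonic globin gene hbbe3 rose from 223 ± 22.9 to 4949 ± 368 CPM (22.2-fold). Its UMIs were present in 46.9 to 74.7% of KO cells per library in the non-blood classes examined, against 0.794 to 6.25% of WT cells. Part of its level in them is therefore free RNA. The classes examined were skeletal muscle, arch mesenchyme, xanthophores, iridophores, melanin pigment cells, endothelial cells, mural cells and hepatocyte or yolk cells. The cardiac myosin light chain gene cmlc1 (0.742 ± 0.706 to 21.9 ± 9.80 CPM, 30.5-fold), pmelb (20.7-fold), the otolith matrix gene stm (4.85 ± 1.08 to 87.2 ± 24.3 CPM, 18.01-fold), ftr43 (21.3-fold) and prtgb (16.8-fold) rose as well. The fast myosin gene myhz1.2 rose 17.6-fold, but moved to -1.998 on the log2 scale with the automatic doublet threshold (adjusted p = 0.00340). A pair of further rises is uncertain because each gene shares its symbol with a second copy between which reads can be split. These were rrm2 with identifier ENSDARG00000078069, 210-fold higher at 144 ± 2.4996 CPM, and actc1a with identifier ENSDARG00000076126, with 1 UMI in WT and 10.5 ± 1.101 CPM in KO (ratio 2637, interval 473 to 104180).

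In all, 7165 of 20849 tested genes were higher and 7309 lower in KO heads (69.4% called, edgeR), and 5611 of these changed more than 2-fold, 1979 up and 3632 down. The large number of calls goes with libraries whose replicates differ little, so a call does not imply a large change. Cells of the genotypes also separated in the clustering, with 20 of 54 clusters drawn over 90% from 1 genotype and holding 68.9% of WT and 42.3% of KO cells, so whole-head values mix changes within cells with changes in which cells were present.

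Genes of differentiated neurons and photoreceptors fell together in whole heads. Of 62 axon and synapse genes, 55 fell and 2 rose (median log2 fold change -1.56, camera adjusted p = 5.45e-13), among them grin1b, an NMDA receptor subunit (-3.26), slc6a1a, a GABA transporter (-2.99), syn1 (-2.52) and sv2a (-2.09). Of 46 photoreceptor genes, 41 fell and 1 rose (median -3.50, adjusted p = 6.2e-12), including tulp1a (-3.23). This fall went with few KO cells in the cone-like cluster 20 (508 and 382 WT, 17 and 15 KO cells). The list was still called by camera at the preset correlation with equal class numbers (adjusted p = 0.0113). Glycolysis and hypoxia genes fell in 31 of 49 cases and rose in 8 (median -0.85, adjusted p = 0.00124), with pfkpa (-2.24), the neuronal enolase gene eno2 (-2.25), aldocb (-1.78) and eno1a (-1.47) changing most clearly. With equal class numbers the axon and synapse median shrank to -0.68. With an estimated correlation these calls were lost, at adjusted p = 0.42 with an estimated correlation for axon and synapse genes and 0.439 for the other lists.

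The lists of cell cycle genes and of Notch, Hedgehog, Wnt and Fgf signalling were higher in KO heads at the preset correlation. All 43 tested mitosis genes rose (median 0.81, adjusted p = 1.53e-11), among them aurka (1.21), kifc1 (1.12), plk1 (1.08) and mki67 (0.75). Of 40 replication and S phase genes, 38 rose (median 0.97, adjusted p = 1.99e-11), led by cdt1 (1.66), fen1 (1.35), cdc6 (1.31) and prim2 (1.25). Both lists had adjusted p = 0.464 with an estimated correlation. Neither call held when equal numbers of cells per class were drawn (adjusted p = 0.938 and 0.469), and mki67 was then at -0.15. Notch genes rose in 30 of 37 cases and fell in 2 (median 1.05, adjusted p = 1.55e-08), with the ligand gene dlb (48.4 to 177 CPM), the receptor genes notch1a (68.9 to 204 CPM) and notch3 (140 to 353 CPM), and the target her6 (75.8 to 209 CPM). Hedgehog genes rose in 20 of 24 cases (median 0.64, adjusted p = 4.95e-05), among them the signal transducer smo (1.62), gas1b (1.94), scube2 (1.42) and nkx6.1 (1.39). Of 46 Wnt genes, 31 rose and 6 fell (median 0.59, adjusted p = 0.000145), with dkk1a (3.65), fzd7a (0.99) and wnt11 (0.94) higher and tcf7l2 (-1.41) lower. Of 30 Fgf genes, 19 rose and 3 fell (median 0.46, adjusted p = 0.004), including the Fgf targets etv4 (1.68), etv5b (1.45) and dusp6 (1.42) and the receptor gene fgfr1b (1.24). The 4 signalling lists had adjusted p = 0.42 with an estimated correlation, and with equal class numbers the Wnt (0.42) and Hedgehog (0.211) calls were lost and the Notch median shrank to 0.41.

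BMP genes were higher in whole KO heads. Of 40 BMP ligand, receptor and antagonist genes, 23 rose and 7 fell (median 0.51, adjusted p = 0.00412, and adjusted p = 0.42 with an estimated correlation). The ligand gene bmp2b rose from 6.39 ± 0.143 to 19.02 ± 0.732 CPM, the type I receptor gene bmpr1ba from 6.05 ± 0.148 to 17.9 ± 0.387 CPM, the antagonist gene fsta (follistatin) from 29.2 ± 0.427 to 66.3 ± 1.71 CPM and the signal transducer smad5 from 20.0 ± 0.853 to 42.05 ± 0.308 CPM. Of 24 BMP response genes, 16 rose and 4 fell (median 0.82, adjusted p = 0.00399, and adjusted p = 0.439 with an estimated correlation). Most clearly raised were msx1b (14.7 ± 0.113 to 76.9 ± 0.913 CPM), gata2a (22.1 ± 0.753 to 70.6 ± 3.44 CPM), hey2 (1.77 on the log2 scale) and the inhibitory Smad gene smad6b (2.29-fold).

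Jaw patterning genes rose in 32 of 46 cases and fell in 6 (median 0.62, adjusted p = 0.000129, and adjusted p = 0.42 with an estimated correlation), among them nr2f5 (1.72), jag1b (1.48), six1a (1.04) and pou3f3a (0.93). Neural crest specification genes rose in 16 of 25 cases and fell in 5 (median 0.70, adjusted p = 0.0159, and adjusted p = 0.439 with an estimated correlation). Here foxd3 and twist1a (both 1.32) were higher and tfap2c (-1.81) lower. Pigment cell genes rose in 15 of 31 cases and fell in 3 (median 0.44, adjusted p = 0.0204, and adjusted p = 0.75 with an estimated correlation). Of these, aox5 (1.73), mycla (1.66) and impdh1b (1.18) were higher and pnp4a (-1.75), an iridophore enzyme gene, lower. DNA methylation machinery genes, a list that includes the targeted genes, rose in 15 of 24 cases and fell in 4 (median 0.48, adjusted p = 0.0311, and adjusted p = 0.439 with an estimated correlation). The demethylation factor genes gadd45ab (1.80) and gadd45bb (1.51) were higher and the methyltransferase gene dnmt3ab (-1.32) lower. With equal class numbers, the neural crest (0.305), pigment (0.0676) and methylation (0.315) calls were lost.

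Stress genes were also higher in KO heads. Heat shock and unfolded protein response genes rose in 27 of 37 cases and fell in 8 (median 0.66, adjusted p = 0.000145, and adjusted p = 0.42 with an estimated correlation). Levels of hsp70l went from 2031 ± 21.8 to 7441 ± 49.99 CPM, of hsp70.1 from 975 to 3182 CPM and of hsp70.3 from 2714 to 7550 CPM, and hspa8b rose by 3.04 on the log2 scale. The Hsp70 genes are similar copies among which reads can be split. Genes of the p53 response rose in 15 of 24 cases and fell in 6 (median 0.67, adjusted p = 0.0116, and adjusted p = 0.439 with an estimated correlation), including epha2a (2.65), phlda3 (1.45), ccng1 (1.41) and isg15 (3.57), which is also an interferon response gene.

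A further 9 lists were not called in whole heads. Cartilage genes rose in 10 and fell in 14 of 41 cases (median -0.09, adjusted p = 0.528), with the aggrecan gene acana falling from 7.67 ± 0.934 to 0.105 ± 0.0267 CPM and col11a2 by 1.87 on the log2 scale, while hapln1a (0.81) and sox9a (0.74) rose. Osteogenesis genes rose in 7 and fell in 3 of 18 cases (median 0.20, mean -0.12, positive test, adjusted p = 0.436), with dlx5a (0.60), postnb (0.58) and sparc (0.32) higher and ifitm5 (-2.27) lower. With equal class numbers postnb was at -0.28 and sparc at -0.32, and col11a2 was at 0.36. Retinoic acid genes rose in 15 and fell in 9 of 28 cases (adjusted p = 0.152), with the degrading enzymes cyp26a1 (2.37) and cyp26c1 (1.90) and dhrs3b (2.00) higher and the binding protein crabp1a (-2.30) lower. Hox genes rose in 15 and fell in 15 of 42 cases (adjusted p = 0.68), with hoxb1b (1.93) and hoxa2b (1.16) higher and hoxb5a (-1.59) and hoxb8a (-1.07) lower. Immediate early genes rose in 22 and fell in 21 of 47 cases (adjusted p = 0.449), with atf3 going from 447 to 2514 CPM and mych rising 4.94-fold, while npas4a, which is induced by neuronal activity, went from 226 to 20.1 CPM and sik1 fell by 1.59. Interferon genes rose in 12 and fell in 8 of 29 cases (adjusted p = 0.213), with irf1b (2.36), irf9 (2.19) and nfkb2 (1.48) higher and the chemokine gene ccl34a.4 (31.9-fold) lower. Nuclear oxidative phosphorylation genes rose in 14 and fell in 22 of 71 cases (adjusted p = 0.466), with cox6a2 (-3.82), cox6b1 (-1.27) and ndufb3 (-0.45) lower and atp5mc3a (0.49) higher. Germline genes rose in 8 and fell in 4 of 20 cases (adjusted p = 0.351), with figla (3.27) and nanos3 (2.67) higher at under 1 CPM and tdrd7b (-2.04) and sycp3 (-1.27) lower. Blood stem cell genes rose in 12 and fell in 4 of 18 cases (adjusted p = 0.0624), with gata2a (1.67), meis1a (0.61, but -0.0877 with equal class numbers) and lmo2 (0.56) higher and ccr9a (-3.29) lower.

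Adjusted over the list alone, the whole-head counts were as over all genes except for osteogenesis (6 rose), oxidative phosphorylation (11 rose, 21 fell), blood stem cell (13 rose) and photoreceptor genes (42 fell). With the preset correlation, camera called 14 lists higher and 3 lower. With an estimated correlation it called 0 of the 26 (lowest adjusted p = 0.42, with 4 lists at an unadjusted p under 0.05), while fry called 20.

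Among the 35 marker lists, those of macrophages or microglia (17 of 20 fell, median -2.24, adjusted p = 4.95e-05), neurons (23 of 26 fell and 2 rose, 1.42e-07), retinal neurons (17 of 21 fell and 2 rose, 0.000229) and periderm (11 of 20 fell and 1 rose, 0.0465) were lower. Higher were the markers of neural progenitors (13 of 17 rose and 1 fell, 0.000349), arch mesenchyme (17 of 21 rose and 2 fell, 0.000732), skeletal muscle (20 of 22 rose and 1 fell, 0.000229), cardiac muscle (8 of 10 rose, 0.00232), endothelial cells (12 of 22 rose and 2 fell, 0.0269), pharyngeal endoderm (11 of 19 rose and 2 fell, 0.0138) and xanthophores (7 of 10 rose and 1 fell, 0.03). Adjusted over the list alone, counts moved by 1 in the macrophage list (18 fell) and the skeletal muscle list (2 fell). These 11 calls were lost with an estimated correlation. Their lowest adjusted p = 0.42 with an estimated correlation, the highest 0.756, and 1 list was at an unadjusted p under 0.05, while fry called 18 of the 35. With equal class numbers, 5 of the 11 were lost, namely macrophage (adjusted p = 0.246), retinal neuron (0.107), arch mesenchyme (0.0743), pharyngeal endoderm (0.381) and endothelial markers (0.466, with a negative direction). The gene list changes above thus went with lower neuronal, retinal, macrophage and periderm markers and with higher progenitor, mesenchyme and muscle markers.

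**Figure D2:**
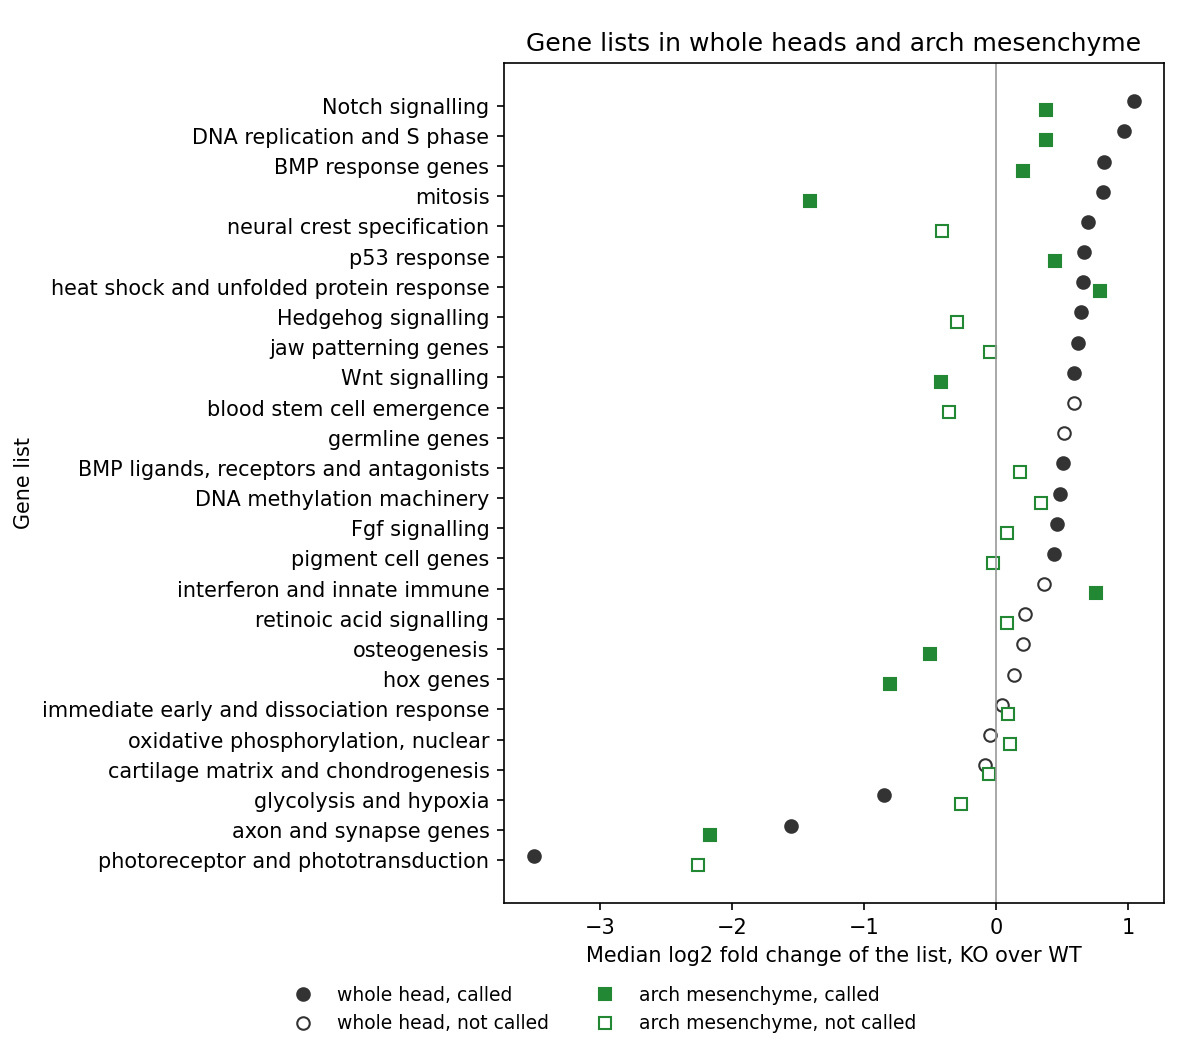
Median log2 fold change, KO over WT, of the 26 gene lists in whole heads (circles) and the 25 tested in arch mesenchyme (squares), with filled symbols for lists called by camera at the preset correlation and open ones for the rest. Mitosis genes lie at 0.81 in whole heads and at -1.41 in arch mesenchyme, and axon and synapse genes lie below 0 in both.

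Within the arch mesenchyme class, the cells marked by prrx1 and twist1 genes, the heat shock list was higher, the mitosis list lower and the BMP response list higher with the preset correlation. None of these held with an estimated correlation (adjusted p = 0.238, 0.428 and 0.479), and 11 of 22 BMP response genes were not called. The class held 98 and 79 WT cells and 503 and 519 KO cells, with 84.2% of its WT and 94.9% of its KO cells in cluster 14 and the rest in cluster 52. Markers that named cluster 14 included dlx genes. Those of cluster 52 did not, and 0 of its top 10 genes were markers of the class. Of its 20 tested markers, 6 changed at least 2-fold inside it. Cluster 18, a head mesenchyme cluster outside the class, held 902 WT and 58 KO cells. The changes below, those of BMP and mitosis genes included, are thus not told apart from differences in which mesenchyme cells the class held. Of 10954 genes tested, 1512 were higher and 1667 lower in KO (edgeR). Among the genes that rose most was hspa8b, at least 17.6-fold higher (0 UMIs in WT, 25.3 ± 1.92 CPM in KO), which is uncertain because this heat shock cognate gene has similar copies. The forkhead gene foxi1 was at least 9.89-fold and hivep3b at least 8.21-fold higher, against 0 WT UMIs. Ratios with 1 to 3 WT UMIs were 112 for the uncertain rrm2 copy ENSDARG00000078069 (interval 38.3 to 544), 58.4 for ifi45 (10.4 to 2312) and 37.4 for esm1 (12.7 to 182). Among those that fell, the matrix gene postna (periostin) went from 72.6 ± 25.4 to 1.29 ± 0.0463 CPM (54.9-fold), ecrg4a from 64.0 ± 40.3 to 0.375 ± 0.0626 CPM (155-fold), rgs5a from 83.5 ± 1.08 to 2.403 ± 0.357 CPM (34.03-fold) and adgrb1b from 17.9 ± 0.475 to 0.623 ± 0.288 CPM (28.0-fold). Since adgrb1b was a top gene of the neuron-like cluster 1 (2145 and 1708 WT, 64 and 80 KO cells), its fall was not told apart from free RNA. The gene stoml3b was at least 44.6-fold lower, and gnb3a had a ratio of 147 (23.8 to 6037). UMIs of gnb3a, a top gene of the retinal cluster 15, were found in 15.3 and 7.59% of WT arch mesenchyme cells at median depths of 9785.5 and 10828 UMIs. In WT erythroid cells, which should lack it, the shares were 12.9 and 7.07% at 14602.5 and 15291.5 UMIs, so its level in mesenchyme is read as background. In arch mesenchyme, tet3 fell from 122 ± 4.72 to 62.9 ± 5.27 CPM (adjusted p = 0.000672), while tet2 was at 59.3 ± 8.18 and 54.3 ± 4.48 CPM (adjusted p = 0.579) and tet1 at 3.85 and 5.58 CPM (adjusted p = 0.447). Leaving out KO replicate 1 or KO replicate 2 lowered the counts to 868 and 924 higher and 911 and 924 lower, and DESeq2 called 779 and 959.

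BMP pathway genes moved in both directions in arch mesenchyme. Of 29 tested ligand, receptor and antagonist genes, 6 rose, 3 fell and 20 were not called (median 0.18, camera adjusted p = 0.345). The receptor gene bmpr1ba rose from 22.2 ± 2.99 to 67.3 ± 7.57 CPM, bmp4 from 12.1 ± 2.19 to 31.1 ± 1.23 CPM, bmp2b from 37.3 ± 18.9 to 81.6 ± 13.02 CPM, the receptor-regulated Smad gene smad9 from 8.67 ± 2.63 to 23.7 ± 2.497 CPM, and the antagonist genes nog1 and nog2 by 0.99 and 0.84 on the log2 scale. The nog2 call was lost in 5 alternatives, among them DESeq2. Another noggin gene, nog3, fell from 33.7 ± 7.80 to 14.03 ± 0.275 CPM, and twsg1a, which encodes a BMP-binding protein, from 34.7 ± 2.33 to 16.4 ± 1.19 CPM. Of 22 BMP response genes, 9 rose and 2 fell (median 0.20, adjusted p = 0.0339), and adjusted over the list alone 10 rose and 2 fell. That list had adjusted p = 0.479 with an estimated correlation and 0.0543 by fry. The direct target id1 rose from 886 ± 224 to 2601 ± 36.1 CPM (adjusted p = 0.00013), id2a from 135 ± 18.6 to 304 ± 6.40 CPM, msx1b from 50.1 ± 24.0 to 194 ± 18.4 CPM, msx2b from 25.2 ± 11.2 to 58.2 ± 1.67 CPM, and msx3 and the inhibitory Smad gene smad6a by 1.28 and 1.18. Against this direction, id4 fell from 32.3 ± 1.67 to 10.2 ± 0.568 CPM and the pseudoreceptor gene bambib from 34.7 ± 3.69 to 15.4 ± 1.39 CPM. Pooling all head mesenchyme clusters, an alternative chosen after seeing the data, kept the call of the response list (12 of 22 rose and 5 fell, adjusted p = 0.0104, and adjusted p = 0.372 with an estimated correlation) but put bmp4 at -0.37.

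**Figure D3:**
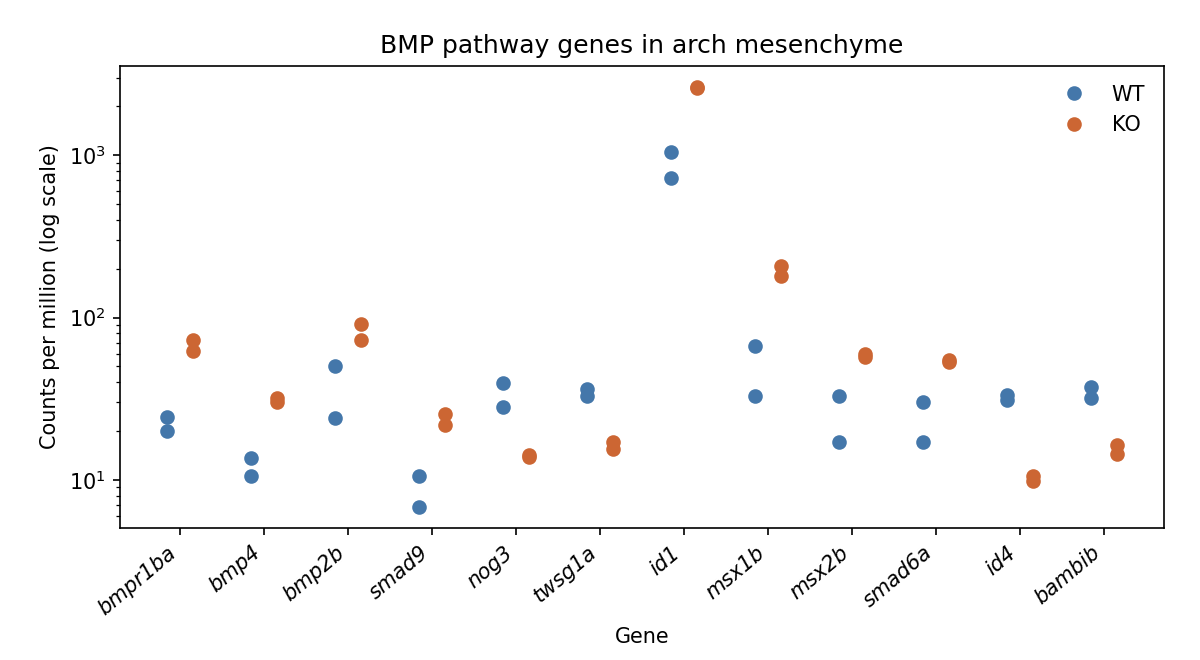
Levels of 12 BMP pathway genes called in arch mesenchyme, in CPM on a log axis, with 1 point per library (2 WT, 2 KO). For 8 genes both KO points lie above both WT points, and for nog3, twsg1a, id4 and bambib both lie below.

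Among the other lists in arch mesenchyme, mitosis genes fell in 42 of 43 cases (median -1.41, adjusted p = 7.08e-73, and adjusted p = 0.428 with an estimated correlation). Expression of top2a went from 590 ± 22.6 to 131 ± 4.86 CPM and cenpf (-2.23), cenpe (-2.19) and nusap1 (-1.92) fell as clearly. Replication and S phase genes instead rose in 19 of 39 cases and the other 20 were not called (median 0.38, adjusted p = 3.08e-05, and adjusted p = 0.479 with an estimated correlation), with mcm2 (1.32), mcm5 (1.24), mcm4 (1.22) and mcm3 (1.13) higher. Heat shock genes rose in 21 of 35 cases and fell in 5 (median 0.79, adjusted p = 2.07e-17, and adjusted p = 0.238 with an estimated correlation). In this list hsp70l went from 647 ± 109 to 5312 ± 124 CPM and hsp70.1 from 367 ± 31.6 to 2322 ± 6.70 CPM, and hsp70.2 (2.13) and hsp90aa1.2 (1.49) rose. Genes of the p53 response rose in 10 of 20 cases and fell in 4 (adjusted p = 0.0235), including epha2a (2.62), phlda3 (1.61), ccng1 (1.17) and rps27l (1.08). Notch genes rose in 7 of 31 and fell in 2 (adjusted p = 0.0235), with dlb (3.09), her15.2 (2.54), notch1a (1.62) and her6 (0.93) higher. Both had adjusted p = 0.479 with an estimated correlation. Interferon genes rose in 4 of 10 cases (adjusted p = 0.0129, and adjusted p = 0.497 with an estimated correlation), namely irf1b (1.15), irf9 (1.02), stat1a (1.00) and cxcl18b (0.89).

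Lower lists in arch mesenchyme included osteogenesis genes, of which 4 of 9 fell and 1 rose (median -0.50, adjusted p = 0.0235). The collagen I genes col1a2 (1604 ± 712 to 484 ± 34.5 CPM), col1a1b (-1.53) and col1a1a (-1.34) and the osteonectin gene sparc (1091 ± 156 to 465 ± 7.99 CPM) made up the 4. Top genes of cluster 52 included col1a1b and col1a2. That cluster held 15.8% of the WT and 5.09% of the KO cells of the class, so the fall of these genes is not told apart from this shift. Wnt genes fell in 12 of 35 cases and rose in 2 (median -0.42, adjusted p = 0.00588), with the Wnt antagonist genes frzb (-3.21), sfrp2 (-1.59) and sfrp5 (-1.11) and the ligand gene wnt11 (-1.45) among those that fell, although sfrp5 was at 0.22 in the pooled head mesenchyme. Axon and synapse genes fell in 25 of 32 cases and rose in 1 (median -2.17, adjusted p = 5.79e-10), with sypa (-2.46), sv2a (-2.44) and snap25a (-2.35) lower. Neuronal transcripts in mesenchyme were not told apart from free RNA, at which level gnb3a lay, so this fall is not read as a change within these cells. The 3 lists had adjusted p = 0.479 with an estimated correlation. Hox genes fell in 11 of 25 cases and rose in 3 (median -0.80, adjusted p = 0.04, and adjusted p = 0.556 with an estimated correlation), including hoxb8a (-2.14), hoxb5a (-1.77), hoxb3a (-1.18) and hoxd4a (-1.16). Since hoxb8a and hoxb5a were top genes of cluster 13, with neuron as its best match, their falls were not told apart from free RNA.

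No call was made in arch mesenchyme for jaw patterning genes (10 of 42 rose and 5 fell, median -0.05, mean 0.02, adjusted p = 0.809), in which nr2f5 (1.14) and prrx1b (1.13) rose and foxl1 (-2.52) and meis1b (-0.93) fell. The same held for cartilage genes (2 of 26 rose and 8 fell, 0.45), with sox9a (1.22, but -0.27 in the pooled head mesenchyme) higher and col9a1a (-2.90), col11a1b (-1.16) and hapln1a (-0.73) lower. Neural crest genes rose in 5 and fell in 5 of 20 cases (0.396), with snai2 (2.09) higher and pax7a (-2.67), tfap2a (-1.84) and twist1b (-1.12) lower. Fgf genes rose in 3 and fell in 7 of 22 cases (median 0.08, mean -0.01, 0.658), with the target dusp6 (1.45) higher and fgfrl1a (-1.03), spry2 (-0.94) and spry4 (-0.74) lower. Hedgehog genes rose in 2 and fell in 6 of 19 (0.099), with hhip (-1.21), foxf2a (-1.18), gli3 (-0.79) and boc (-0.78) lower. Retinoic acid genes rose in 5 and fell in 6 of 23 (median 0.08 with a negative test, 0.809), with cyp26a1 (3.68) and dhrs3b (3.18) higher and rbp4 (-3.83) lower. Methylation genes rose in 8 and fell in 2 of 23 (0.0925), with mbd2 (1.85) and gadd45ba (1.03) higher and dnmt3ab (-1.33) lower. Pigment genes rose in 4 and fell in 3 of 12 (median -0.03 with a positive test, 0.757), with mycla (1.41), paics (1.16) and atic (0.95) higher. Immediate early genes rose in 11 and fell in 12 of 45 (0.809), with fosl2 (1.93), atf3 (1.88) and klf6a (0.99) higher and fosb (-1.58) lower. Glycolysis genes rose in 3 and fell in 13 of 32 (0.116), with igfbp1a (3.65) higher and eno2 (-2.96), eno1a (-1.25) and gpia (-1.14) lower. The fall of the neuronal gene eno2 was not told apart from free RNA, as for the synapse genes. Oxidative phosphorylation genes rose in 13 and fell in 6 of 68 (0.116), with uqcrfs1 (0.79), cycsb (0.75) and atp5mc3a (0.67) higher and ndufa6 (-0.65) lower. Of 5 blood stem cell genes, cbfb (-0.54) and meis1a (-0.36) fell (0.425), but these calls did not hold in 8 and 7 alternatives, and meis1a was at 0.32 in the pooled head mesenchyme. Of 5 photoreceptor genes gnb3a and crx (-2.72) fell (0.0552), with crx no longer called in 3 alternatives. Germline genes were too few to test.

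Adjusted over the list alone, arch mesenchyme counts differed from those over all genes in mitosis (43 fell), S phase (21 rose), heat shock (22 rose, 6 fell), Notch (8 rose), Wnt (3 rose, 13 fell), hox (4 rose), osteogenesis (5 fell), axon and synapse (26 fell), Fgf (5 rose, 9 fell), retinoic acid (7 rose), methylation (3 fell), immediate early (13 rose, 13 fell), glycolysis (4 rose) and photoreceptor genes (4 fell). With an estimated correlation, camera called 0 of the 25 lists, with 2 at an unadjusted p under 0.05, and fry called 2, which were mitosis (0.0376) and heat shock (0.00546).

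Cartilage genes were lower in sums over all head mesenchyme clusters. Cluster 40, named chondrocyte-like, held 121 and 107 WT cells and 0 of 23219 KO cells, which allows up to 0.0129%. That bound is for this cluster alone. With doublets kept, the chondrocyte-like cluster held 1 KO cell. At resolution 2, a further, unnamed cluster with chondrocyte as its best match held 444 and 307 WT and 26 and 32 KO cells. With no KO cells in cluster 40, neither its genes nor its markers could be tested within the class, and its share was therefore not compared. In the pooled head mesenchyme (clusters 14, 18, 24, 35, 40 and 52, an alternative chosen after seeing the data), which made up 6.44 and 6.92% of WT and 7.50 and 7.89% of KO cells (adjusted p = 0.122), 27 of 38 cartilage genes fell and 7 rose. The genotypes filled different clusters of this pool, with 902 WT and 58 KO cells in cluster 18 and 149 WT and 970 KO cells in cluster 14, so pooled changes are not told apart from changes in which mesenchyme cells were present. Their median was -0.83 (adjusted p = 3.3e-12, and adjusted p = 0.454 with an estimated correlation), and adjusted over the list alone 28 fell and 7 rose. Aggrecan (acana) went from 129 ± 13.95 to 0.733 ± 0.232 CPM, the link protein gene hapln1b from 165 ± 18.7 to 16.9 ± 0.539 CPM, the collagen IX gene col9a1a from 315 ± 51.9 to 30.6 ± 1.58 CPM, and wwp2 by -2.24. Picked after their values were seen, col2a1a went from 1456 ± 293 to 459 ± 57.2 CPM and matn1 from 50.8 ± 20.2 to 0.287 ± 0.264 CPM, while matn3a (3.67), col9a1b (3.15) and runx3 (1.63) rose.

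In the same pooled mesenchyme, with its clusters split by genotype, osteogenesis genes fell in 9 of 15 cases and rose in 2 (median -0.83, adjusted p = 0.027, and adjusted p = 0.454 with an estimated correlation), with sparc (-1.05), col1a2 (-1.10) and col1a1b (-0.99) lower and dlx5a (1.32) higher. Jaw patterning genes rose in 24 of 46 and fell in 8 (adjusted p = 0.00613, and adjusted p = 0.454 with an estimated correlation), with dlx4b (1.74), nr2f5 (1.68), dlx5a (1.32) and dlx3b (1.28) higher. BMP ligand, receptor and antagonist genes rose in 12 of 35 cases and fell in 9 (median 0.10, mean -0.10, adjusted p = 0.881), with smad9 (1.44), bmp6 (1.31), bmpr1ba (0.84), acvr1l (0.81) and nog1 (0.69) higher and chrd (-2.10), nog3 (-1.51) and twsg1a (-0.91) lower. Among BMP response genes, msx2b (2.00), msx1b (1.45), msx3 (1.40), dlx3b (1.28), id1 (1.26), smad6a (1.17) and id2a (1.07) were higher and id4 (-1.82) lower. Mitosis genes, lower in the arch mesenchyme class, rose here in 26 of 43 cases and fell in 4 (adjusted p = 0.00344, and adjusted p = 0.372 with an estimated correlation), led by hmgb2b (0.90) and hmgb2a (0.71). The pooled cells had 3788 genes higher and 3754 lower of 14051. Of the 10951 genes tested in both, 1401 were higher and 1181 lower in both, and 164 went in opposite directions.

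The other 11 testable classes each held genes that were present in 1 genotype and near absence in the other. In cluster 19 (1901 genes higher, 2024 lower), named cranial sensory neuron from the fixed markers, the acetylcholine genes slc5a7a, slc18a3a and chata among its top genes are those of motor neurons, so its identity is uncertain. There vipb was at least 393-fold lower, from 269 ± 51.3 CPM to 0 KO UMIs, and the scg5 copy ENSDARG00000077045 at least 69.3-fold higher, which is uncertain for the same reason as rrm2. In retinal progenitors (2408 and 2388), prkcq had a ratio of 110 (interval 19.6 to 4345) and gnb3a fell 281-fold, from 97.04 ± 12.8 CPM, which was not told apart from free RNA of other retinal cells. In skeletal muscle (1346 and 1348), cmlc1 was at least 952-fold higher at 460 ± 292 CPM, but UMIs of it were found in 2.93 and 5.73% of the KO cells alone, and the call was lost with doublets kept. There gnb3a was at least 61.1-fold lower, with UMIs in 14.04 and 10% of the WT cells, which is read as background. Mural cells (349 and 396) had runx3, a transcription factor gene, at least 49.7-fold higher and rasl12 at least 18.9-fold lower. Endothelial cells (905 and 984) had hspb11 at least 31.9-fold higher and sc:d189 at least 77.8-fold lower, both lost without the filter on low counts. Hepatocyte or yolk cells (149 and 118) had the uncertain rrm2 copy ENSDARG00000078069 at least 26.9-fold higher, a call lost without either KO replicate, and crp3 at least 35.98-fold lower. In the oligodendrocyte lineage (392 and 576), the retinoic acid degrading enzyme gene cyp26b1 had a ratio of 125 (21.3 to 5064), a call lost with doublets kept. There vsx1 was at least 24.8-fold lower, but this gene marks retinal bipolar cells and was not told apart from background in WT, and the call was lost without either KO replicate.

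Pigment and blood classes lay partly in different clusters by genotype. Iridophores, the reflecting pigment cells, lay in cluster 49 for 80% of WT cells and in cluster 42 for all KO cells. In them 1944 genes were higher and 1996 lower in KO, with pth1a, a parathyroid hormone gene, at least 74.97-fold higher and hsc70, which has similar copies too and is uncertain, at least 132-fold lower. Melanin pigment cells (882 and 980), with 21.5% of KO but 0.573% of WT cells in cluster 53, had tm6sf2 at least 77.5-fold higher. Since tm6sf2 is a top gene of cluster 53, this difference is not told apart from one in which pigment cells were present. There gnb3a was at least 37.6-fold lower, again at a background share of 14.8 and 5.56% of WT cells (median depths 1954 and 1973 UMIs). Xanthophores, the yellow pigment cells (874 and 1092), formed 1 cluster here but at resolution 2 fell into cluster 47 (186 and 103 WT, 0 and 1 KO cells) and cluster 32 (35 and 25 WT, 276 and 255 KO cells). They had the interferon response gene isg15 at least 9.52-fold higher and camkvb at least 18.2-fold lower. Erythroid cells lay in cluster 3 for 98.5% of WT cells and in clusters 9 and 39 for 86.4 and 11.8% of KO cells. Of their genes, 2296 were higher and 2432 lower, with the chemokine receptor gene cxcr4a falling 185-fold, from 21.5 ± 4.68 CPM, and the rrm2 copy at least 262-fold higher. Over the 22 numbered clusters, the calls added up to 21312 higher and 21224 lower, counting a gene once per cluster. Without KO replicate 1 they were 14154 and 13488, without KO replicate 2 there were 13263 lower, and DESeq2 gave 12337 and 11143.

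Of the 5 classes whose shares could be compared under a rule set after seeing the data, 3 were larger in KO. The other 11 named classes were not compared, so these shares do not describe the direction of change across the head. The rule could not admit a class with fewer than 20 cells in any library, so it left out classes with few KO cells. Those were macrophages or microglia (103 and 77 WT, 16 and 17 KO cells), neutrophils (50 and 51, 16 and 11) and chondrocytes (121 and 107, 0 and 0). Neural crest or glial crest cells were left out for few WT cells (19 and 15, against 55 and 40 in KO). Endothelial cells made up 0.456 ± 0.0669% of WT and 0.855 ± 0.111% of KO cells (log2 fold change 0.89, adjusted p = 0.00356, edgeR), xanthophores 1.37 ± 0.217 and 2.29 ± 0.0190% (0.73, adjusted p = 0.00318) and iridophores 0.517 ± 0.0192 and 0.746 ± 0.0274% (0.52, adjusted p = 0.0204). Shares of skeletal muscle cells were 1.67 ± 0.0642 and 2.01 ± 0.0170% (0.27, adjusted p = 0.0932) and those of hepatocyte or yolk cells 0.494 ± 0.0528 and 0.619 ± 0.0575% (0.32, adjusted p = 0.151). Xanthophores and iridophores were each split between clusters by genotype, as given above, so their shares compare cells that differ in state. The iridophore call was lost with doublets kept and with any 1 library left out. With TMM scaling over classes, edgeR called 0 shares higher (0 at an unadjusted p under 0.05) and 0 lower (1 at an unadjusted p under 0.05), and the iridophore difference turned to -0.11.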

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

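Most results were the same under the alternatives. The automatic doublet threshold, the pooled head mesenchyme, whole heads without erythroid cells or clusters of low UMI count, and the crossed block were chosen after seeing the data. The cause of the changes below was not tested. Leaving out 1 library leaves 1 in its genotype, and that lone library is assumed to vary like the other genotype.

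The log2 fold change of tet2 ran from -0.65 to -0.50 over all alternatives and that of tet3 from -1.15 to -0.85, with -0.65 to -0.57 and -1.11 to -1.05 when 1 library was left out. In whole heads, 5968 to 6746 genes were higher and 5973 to 6821 lower with a library left out, and all alternatives gave 4832 to 7367 and 4891 to 7526. DESeq2 called 6485 higher and 6386 lower.

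In arch mesenchyme, DESeq2 called 779 genes higher and 959 lower, and the pooled head mesenchyme gave 3788 and 3754. With a library left out, counts ran from 868 to 1343 higher and from 911 to 1332 lower. The lowest came without KO replicate 1 (868 and 911), and without KO replicate 2 there were 924 and 924.

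Over 9 other named classes, counts of 10689 and 11550 became 5659 and 6200 with DESeq2, and 8188 to 10430 and 8753 to 11257 with a library left out. Over the 22 numbered clusters, DESeq2 gave 12337 and 11143, and leaving out a library gave 14154 to 18954 higher and 13263 to 17501 lower. Without KO replicate 1 there were 14154 higher and 13488 lower, and without KO replicate 2 there were 13263 lower.

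Of the compared shares, 3 were higher in KO at first, 0 with TMM over classes (0 at an unadjusted p under 0.05, and 1 lower) and 2 with doublets kept or with any library left out, the iridophore call being the one lost. The iridophore share turned to -0.11 under TMM over classes (adjusted p = 0.609).

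With an estimated correlation, camera called 0 lists higher and 0 lower in whole heads, where 4 had an unadjusted p under 0.05 and fry called 17 higher and 3 lower. The BMP ligand list then had adjusted p = 0.42 and the response list 0.439. With a library left out, 13 to 14 lists were higher and 3 lower, and these 2 lists had 0.00188 to 0.00744 and 0.00188 to 0.00444. In arch mesenchyme it called 0 lists higher and 0 lower, with 2 at an unadjusted p under 0.05, and fry called 1 higher and 1 lower. Leaving out a library gave 3 to 7 higher, with 3 without KO replicate 1, and 5 lower. The arch response list had 0.479 with an estimated correlation, 0.0543 by fry and 0.000407 to 0.0157 with a library left out, and the ligand list 0.162 to 0.438.

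Some single genes reversed. The automatic doublet threshold put myhz1.2 at -1.998 (adjusted p = 0.00340). With equal class numbers in whole heads, col11a2 moved to 0.36, postnb to -0.28, sparc to -0.32, mki67 to -0.15 and meis1a to -0.0877. Without reversing, the whole-head results for acana, ifitm5, ccr9a and tulp1a were not the same in 1 alternative each. In the pooled head mesenchyme, bmp4 moved to -0.37, sox9a to -0.27, sfrp5 to 0.22 and meis1a to 0.32. In arch mesenchyme, the calls of cbfb, meis1a and nog2 did not hold in 8, 7 and 5 alternatives, and that of crx in 3. In other classes, vsx1 and the rrm2 copy of hepatocyte or yolk cells were lost without either KO replicate, cmlc1 in muscle and cyp26b1 with doublets kept, and hspb11 and sc:d189 without the filter on low counts.

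Libraries of equal replicate number did not deviate together, since the differences between replicates 1 and 2 had r = -0.27 between genotypes over 17562 genes. The negative sign would go with a crossed pairing, which the labels do not describe and which stays open. Using the replicate numbers as a block gave 6828 genes higher and 6956 lower in whole heads. A crossed block gave 7298 higher and 7482 lower. Mural cells could not be tested with doublets kept, nor retinal progenitors at resolution 2.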

Other observations

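Blood cells differed in which globins they expressed. Within the erythroid class, which lay in cluster 3 for WT and mostly in clusters 9 and 39 for KO, hbbe3 rose from 1713 ± 312 to 33493 ± 523 CPM (19.6-fold, adjusted p = 6.91e-09, edgeR, n = 2 libraries per genotype). The other globin genes moved less, with hbbe1.1 higher (log2 fold change 0.48, adjusted p = 0.00433) and hbae5 (-1.57), hbbe2 (-1.05), hbbe1.3 (-0.91), hbae3 (-0.43) and hbbe1.2 (-0.32) lower. Globin genes are similar copies, so the division of reads among them is uncertain. The erythroid transcription factor gene gata1a rose from 31.4 ± 4.57 to 69.1 ± 3.76 CPM, while hemgn, which encodes hemogen, fell from 1727 ± 182 to 599 ± 30.1 CPM. The haem synthesis gene alas2 (adjusted p = 0.19) and the anion exchanger gene slc4a1a (adjusted p = 0.461) were not called. Globins made up 12.3 and 12.6% of the kept WT UMIs and 10.02 and 9.71% of the kept KO UMIs.

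Several neuropeptide genes besides vipb and oxt changed in whole KO heads. They form no fixed list, were not tested as a group and were chosen after their values were seen. Expression of npy, which encodes neuropeptide Y, went from 8.70 to 0.542 CPM (log2 fold change -4.00, adjusted p = 0.000114, edgeR), that of the opioid precursor gene pdyn from 9.84 to 0.940 CPM (-3.39) and that of crhb, which encodes corticotropin-releasing hormone, from 6.84 to 1.04 CPM (-2.71). The thyrotropin-releasing hormone gene trh (-3.11) fell too, whereas kiss1 rose by 1.66, and hcrt (adjusted p = 0.427) and pomca (adjusted p = 0.841) were not called. The myelin gene mbpa fell (-5.58), while plp1a rose (1.56). Since plp1a was also a top gene of cluster 2, its rise is not read as a change in myelin. Cluster 2 was unnamed, with neural progenitor as its best match, and held 122 and 111 WT and 1094 and 1016 KO cells.

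The tests of why axon and synapse genes were lower and Notch genes higher in KO heads were chosen after that result was seen, with bounds for developmental stage written before the stage values and those for cell composition and RNA quality after. With equal class numbers, the medians of the axon and synapse and the Notch list shrank to -0.68 and 0.41 and stayed called at the preset correlation (adjusted p = 5.16e-12 and 5.26e-06), although both whole-head calls have adjusted p = 0.42 with an estimated correlation. Composition may therefore explain part of the pattern, but how much cannot be told, because clusters split by genotype cannot be equalised within a class. An earlier stage of KO tissue could explain it too, but without lin28a and nfixb, which had already been seen, early genes had a median above 0 in 23 and late genes below 0 in 32 of 34 classes and clusters (whole heads 0.35 and -1.13), with only 1 to 4 late genes tested in each, which does not decide. A lower RNA quality was not seen in the mitochondrial share (-1.12 points against WT) or the median UMIs (1.19 times WT). However, hbbe1.1 UMIs lay in 91.7 to 99.2% of KO against 44.4 to 59.7% of WT cells per library in the non-blood classes examined. A difference in leaked RNA therefore stays open.

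Copies of rrm2, scg5 and actc1a that were nearly absent in WT rose in KO, and the tests of this were chosen after the result was seen, with bounds written before. Summed over the identifiers of each symbol, the KO over WT ratio was 1.01 for actc1a, so reads or alleles assigned to another copy could account for its rise. For rrm2 (2.11) and scg5 (0.449) the sums cannot tell. The other rrm2 copy did not fall but rose as well, from 169 to 214 CPM. Strain differences between the WT and KO lines, which the labels do not describe, may be a source of such changes and stay open.

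Cardiac muscle genes were higher in KO, and the tests of this were chosen after the result was seen, those of the muscle cells with bounds written after their values. In each KO library 10 cells held together 94.5% of the KO UMIs of myl7, cmlc1 and tnnt2a, so most of these UMIs were not spread across muscle cells. Of these UMIs, 84.8% lay in the skeletal muscle class. The 10 cells were picked by the same UMIs, and in WT such cells held 54.7 and 78.4%. A smaller rise across the other muscle cells therefore stays open. Cells with at least 3 cardiac markers held 97.04%, but they were picked by such genes and their median UMI count of the 3 genes was 0 in both KO libraries, so this test is void. Whether heart cells were carried along in the dissection stays open.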
